A study of Mus musculus with 6 samples.

How the data were processed

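The series holds 6 Agilent single-colour arrays of total RNA from mouse J1 embryonic stem cells, 2 each for NT, Thoc2 and Thoc5 siRNA, taken 96 hours after transfection. Per the labels' protocols the cells were kept in ESGRO medium and moved to M10 medium for transfection, and labelling used the Low Input Quick Amp kit. The scanner files hold, per the file headers, the processed signal intensity of each spot after background subtraction and detrending within the array, and the mean and local background intensity. The file headers name Feature Extraction version 9.5.3.1, while the submitters' processing notes name version 11.0. A deposited series table holds log2 values that share their quantiles across the 6 arrays, with a median of 5.82 each. Its Spearman correlation with the processed signal was 1 on every array, so it was read as quantile-normalized log2 of that signal; its direction and scale follow from this, and no header states how it was made.

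Levels were the log2 processed signal minus the 75th percentile of each array. Control spots and spots with outlier flags were left out, spots of a probe were averaged, and a probe was kept if it was well above background on every array of at least 1 group (at least 0.5 of its spots). A gene was represented by its brightest kept probe, which left 19305 genes, 279 of them missing on an array. Of 41174 probes 22951 were named through their accession, 124 through another accession of the probe, 6582 by a current symbol and 3077 by a synonym, in a table made on assembly GRCm38.p6 used for names only; 8440 kept the name in the files. Coordinates are those of the file headers' build mm7. Where all arrays of a group were not well above background, the fold is a bound: the mean of the brighter group against, on each array of the dim group, the higher of the probe's own level and the lowest level among probes well above background.

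Tests were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with the data.table package (1.17.8) for reading, to all 6 arrays with 1 shared spread per gene, 3 residual degrees of freedom and 1.49 prior degrees of freedom. The 4 comparisons were Thoc2 siRNA against NT, Thoc5 siRNA against NT, Thoc5 against Thoc2 siRNA, and the mean of both against NT. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. All tests are two-sided; an exact permutation test of 2 arrays against 2 cannot give a p below 0.333. Errors in the text are the SE of the limma fit with 2 arrays per group.

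The 20 gene lists were THO and TREX, pluripotency, formative and primed epiblast, trophectoderm and trophoblast, extraembryonic endoderm, primitive streak and mesoderm, neuroectoderm, fibroblast and feeder markers, interferon response, p53 targets, heat shock, immediate early, ERK feedback, LIF and BMP targets, integrated stress response and unfolded proteins, cell cycle, retinoic acid and Hox, 2-cell-like and germline, epithelial to mesenchymal, and reference genes. Each was tested with camera at a preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation. Fry, which tests a list's members without comparing them with other genes, was run beside it, with unadjusted p-values. A list's difference is the mean log2 fold change of its members minus the median of all genes. For the fits with slide as a random block and with a trend the same test ran on the moderated statistics. The lists, tests, named-gene rule and most other settings were fixed before the data were examined.

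The rule for named genes took the THO and TREX list, 12 pluripotency and lineage genes whatever their values, for each list its members past the threshold or the member with the smallest p, and the 8 genes with the largest rise and the 8 with the largest fall among genes past the threshold whose groups do not overlap. The last part gave no gene in the tests as designed, so it was applied to the fit with an intensity trend, a choice made after the counts were seen. Members that passed when adjusted over the list alone are named beside it. The values of some single genes are not reported here.

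The fits were tested on simulated data with the genes' real means and spreads (20 draws, 19305 genes). For Thoc2 siRNA against NT limma called 0.188% of genes changed by 1 on the log2 scale, 35.8% of those changed by 2 and 86.9% of those changed by 6, and 0.0209% of unchanged genes; for Thoc5 siRNA these were 0.313%, 34.2%, 86.9% and 0.0202%. A list shifted by 0.5 in the simulated Thoc5 arrays alone was called in 20 of 20 draws there and in 0 of 20 for Thoc2, with 0 other lists called. The simulated genes varied independently of each other, so these draws cannot show how often correlated genes give false list calls. In these draws most changes of 1 on the log2 scale were therefore not called gene by gene. An unadjusted p under 0.05 found 74.8% and 75% of them. For Thoc2 siRNA only 1600, 1600 and 800 gene values carried changes of 1, 2 and 6 over the 20 draws, against 382100 unchanged. The share called after Benjamini-Hochberg adjustment depends on how many genes change, so these shares need not hold on the real arrays.

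Slides held NT replicate 1 with Thoc2 replicate 2, and NT replicate 2 with Thoc5 replicate 2; the 2 further arrays were alone on theirs. Thoc2 replicate 1 was the only array of its scan day, so that day could not be tested. A fixed slide term leaves 0 residual degrees of freedom, so slide entered as a random block with duplicateCorrelation (consensus correlation 0.287). The alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the series table, no filter and a stricter filter on dim probes, the mean of a gene's probes, trend and robust variances, a fold minimum of 1 on the log2 scale, only the arrays compared, slide and replicate blocks, an estimated correlation, and each array left out; where this leaves 1 array in a group, that array is assumed to vary like the other groups. After the data were seen, cyclic loess, leaving out both arrays that stand apart, a crossed block and separate NT arrays were added. Random gene lists matched on mean level, for the p53 targets and for the lists of abundant genes, were also drawn. Shared controls were simulated with 100 draws of unchanged groups; the overlap of calls in such draws, with the same limma fit, was added after the results were seen.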

Results

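Messenger RNA levels were measured on 6 single-colour (Cy3) Agilent expression arrays of J1 cells, a mouse embryonic stem cell line. Total RNA was taken 96 hours after siRNA transfection. The 3 groups held 2 arrays each: a non-targeting siRNA (NT), an siRNA against Thoc2 and an siRNA against Thoc5. Thoc2 and Thoc5 encode subunits of THO, a complex that joins new mRNA and, within the larger TREX assembly, helps to hand it to the export receptor Nxf1. The series title places the arrays in a study of THO and of how mRNA of pluripotency genes leaves the nucleus. Total RNA holds nuclear and cytoplasmic mRNA together, so the arrays measure the level of each mRNA and not its export.

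Each array carried 43379 spots that were not controls, for 41174 probes. The share of spots well above background was 68.8% and 68.3% with NT siRNA, 79.7% and 69.9% with Thoc2 siRNA, and 56.7% and 73.3% with Thoc5 siRNA (replicates 1 and 2). The signal at the 75th percentile was 817 and 905 with NT siRNA, 716 and 733 with Thoc2 siRNA, and 306 and 738 with Thoc5 siRNA, so replicate 1 of Thoc5 siRNA was the dimmest array. Replicate 1 of Thoc2 siRNA stood apart in 2 other ways: its lowest-quartile signal was 17.6 against 2.63 to 10.6 on the other arrays, and it had 880 outlier spots against 63 to 155. The replicates of a group correlated at 0.966 (NT), 0.965 (Thoc2) and 0.976 (Thoc5) across genes. Arrays of different groups correlated at 0.954 to 0.975, so the Thoc5 pair alone lay above that range. The labels do not say whether replicates were separate cultures, so the p-values below measure the spread between arrays.

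The mean levels of the siRNA targets were lower in their own groups, by differences that did not pass the threshold. Thoc2 was at 55.0% of its NT level with Thoc2 siRNA (log2 fold change -0.86 ± 0.28, SE of the limma fit), and was at 101% with Thoc5 siRNA. Thoc5 was at 41.4% of its NT level with Thoc5 siRNA (-1.27 ± 0.27) and at 111% with Thoc2 siRNA. The scaled log2 levels of Thoc2 were 1.33 and 1.43 with NT siRNA, 0.70 and 0.33 with Thoc2 siRNA, and 1.07 and 1.71 with Thoc5 siRNA. Those of Thoc5 were 1.31 and 1.57 with NT siRNA, 1.88 and 1.304 with Thoc2 siRNA, and 0.34 and -0.0018 with Thoc5 siRNA. The adjusted p was 0.302 for Thoc2 and 0.129 for Thoc5, so neither passed the threshold over all genes. With an intensity trend and robust variances in limma the adjusted p of Thoc5 was 0.0458. Compared within the slide that held both groups, the log2 difference was -0.99 for Thoc2 and -1.57 for Thoc5, and with slide as a random block it was -0.85 and -1.36. The Thoc2 probe A_51_P441091 lies on chromosome X from 36919451 to 36919510 and the Thoc5 probe A_51_P467618 on chromosome 11 from 4870150 to 4870210, in the mouse build mm7 that the file headers name. The files do not say which exon each matches. Of 3 further Thoc2 probes, A_52_P154071 gave 51.7% and A_51_P446967 75.3% of NT with Thoc2 siRNA, and A_52_P16694 was not well above background with NT siRNA. The other Thoc5 probe, A_51_P292779, was not well above background on any array.

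**Figure D1:**
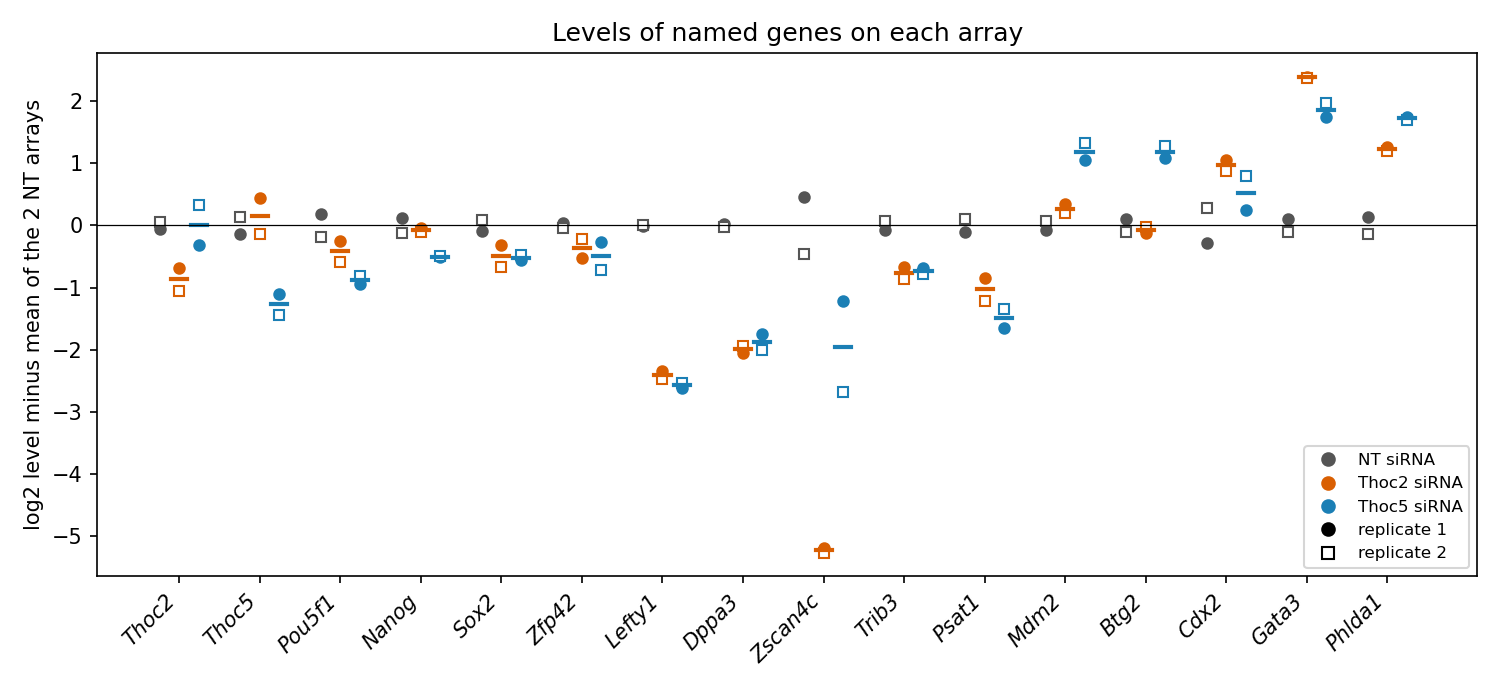
Levels of 16 named genes on each of the 6 arrays, as the log2 level minus the mean of the 2 NT arrays of the same gene; filled circles are replicate 1, open squares replicate 2, and bars the means of the Thoc2 and Thoc5 siRNA groups. Thoc2 lies at -0.86 with its own siRNA and Thoc5 at -1.27 with its own, while Lefty1 and Dppa3 lie below NT on all 4 knockdown arrays and Zscan4c lies lower with Thoc2 siRNA (-5.23) than with Thoc5 siRNA (-1.95).

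What changed with Thoc2 siRNA was asked by setting the 2 Thoc2 siRNA arrays against the 2 NT arrays. The integrated stress response list, genes of amino acid supply and endoplasmic reticulum stress that Atf4 and its partners drive, fell against all other genes: 23 of its 25 measured members lay below 0 (adjusted p = 0.338 with an estimated correlation). Trib3, a pseudokinase induced in stress, was at -0.76 ± 0.16, Psat1, an enzyme of serine synthesis, at -1.03 ± 0.22, and Chac1, which degrades glutathione, at -1.58 ± 0.45. The pluripotency list fell as well, with 24 of 39 members below 0 (adjusted p = 0.532 with an estimated correlation; the call was also lost with other scalings and 2 left-out arrays, given with the test). Lefty1 (-2.40 ± 0.14) and Lefty2 (-2.36 ± 0.28), secreted inhibitors of Nodal, and Dppa3 (-1.99 ± 0.16), a maternal-effect gene of naive cells, fell when p-values were adjusted over the list alone. The median of the pluripotency list differed from that of all genes by -0.153, against -0.305 for its mean. The mean therefore overstates the fall of a typical member. Within the slide that held both groups Lefty1 was at -2.45 and Dppa3 at -1.95. The 2-cell-like and germline list fell in its mean, with 15 of 23 members below 0 and a median of -0.137 (adjusted p = 0.532 with an estimated correlation). Its lowest members were Zscan4c (-5.23 ± 0.59), a marker of the rare 2-cell-like state, and Usp17la (-3.34 ± 0.52), a deubiquitinase gene; within the shared slide they were at -5.72 and -3.69.

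The fixed pluripotency factors moved less than those genes after Thoc2 siRNA. Pou5f1, which encodes Oct4, was at -0.42 ± 0.22, Sox2 at -0.50 ± 0.19, Esrrb at -0.30 ± 0.17, Zfp42 at -0.37 ± 0.22, Klf4 at -0.14 ± 0.16 and Nanog at -0.07 ± 0.16, and none passed the threshold. Pou5f1 stood at -0.23 without NT replicate 1 and at -0.24 without Thoc2 replicate 2, and Sox2 at -0.32 without the latter. Of the lineage genes, Cdx2 of trophectoderm was at 0.97 ± 0.30, Sox1 of neural progenitors at 1.06 ± 0.80, Gata6 and Gata4 of primitive endoderm at 0.60 ± 1.23 and 0.56 ± 0.92, Fgf5 of the epiblast at 0.58 ± 0.37 and T (brachyury) of the primitive streak at 0.20. Gata4 and T changed sign with quantile normalization, to -0.03 and -0.45. Without NT replicate 2, Gata6 stood at -0.97, Gata4 at -0.58, Sox1 at -0.04 and Fgf5 at 0.25. Without NT replicate 1 they stood at 2.16, 1.70, 2.16 and 0.90 in the same order. Gata4 also turned without Thoc2 replicate 2 (-0.13).

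Against all other genes the integrated stress response list was lower by 0.693 in the mean after Thoc2 siRNA (mean difference -0.693, camera adjusted p = 7.17e-07; adjusted p = 0.338 with an estimated correlation). The 2-cell-like and germline list differed by -0.698 (0.0125; adjusted p = 0.532 with an estimated correlation), the pluripotency list by -0.305 (0.0132; adjusted p = 0.532 with an estimated correlation), the cell cycle list by -0.264 (0.0132; adjusted p = 0.532 with an estimated correlation) and the list of reference genes by -0.296 (0.0125; adjusted p = 0.532 with an estimated correlation). The primitive streak and mesoderm list rose by 0.427 (camera adjusted p = 0.0132, and 0.476 with an estimated correlation). Of its 28 members 20 lay above 0, where the median of all genes lay at 0.0599. With slide as a random block these differences were -0.72 (integrated stress response), -0.761 (2-cell-like), -0.33 (pluripotency), -0.254 (cell cycle), -0.311 (reference genes) and 0.437 (mesoderm). Within the shared slide they were -0.825, -0.982, -0.383, -0.169, -0.312 and 0.442 in the same order. Every one of these signs also held with any 1 array left out. The calls of integrated stress response and reference genes stood with any 1 array left out. Pluripotency was not called without NT replicate 2 (-0.241, adjusted p 0.0516) or Thoc2 replicate 2 (-0.317, 0.0973), and cell cycle not without NT replicate 2 (-0.145, 0.234). Mesoderm was not called without Thoc2 replicate 2 (0.474, 0.144), nor 2-cell-like without NT replicate 1 (-0.536, 0.0607) or Thoc2 replicate 2 (-0.493, 0.243). Quantile normalization and cyclic loess each ended the calls of pluripotency (-0.19 and -0.252), cell cycle (-0.164 and -0.216), reference genes (-0.189 and -0.239) and mesoderm (0.207 and 0.319), and normexp background correction that of the 2-cell-like list (-0.248). Trend and robust variances ended the call of mesoderm too (adjusted p 0.0643). With normexp pluripotency stood at -0.804, cell cycle at -0.653 and reference genes at -0.69.

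The other 14 lists did not pass after Thoc2 siRNA. Genes of these lists still passed when p-values were adjusted over the list alone. That does not correct over the 20 lists, and 2817 of all 19305 genes had an unadjusted p under 0.05. Of the ERK feedback list, genes that report signalling through the ERK kinases, 5 of 16 members rose, among them Phlda1 (1.23 ± 0.16), the phosphatase gene Dusp6 (0.81 ± 0.19) and the transcription factor gene Etv4 (0.71 ± 0.16), and 2 fell, Spry1 (-0.72 ± 0.16) and the cyclin gene Ccnd1 (-0.63 ± 0.15). Of neuroectoderm genes Nkx2-2 (1.58 ± 0.32; well above background on 1 of 2 NT arrays) rose, as did the forebrain gene Six3, which was not well above background on the NT arrays and was at least 6.95-fold higher with Thoc2 siRNA. Gata3, a trophoblast transcription factor, was at 2.38 ± 0.17 and Meis2, a homeobox gene under retinoic acid, at 2.11 ± 0.22. The lists' mean differences from all genes, each with its camera adjusted p, were -0.091 (0.634) for THO and TREX, -0.174 (0.0577) for formative and primed epiblast, -0.0477 (0.634) for trophectoderm and trophoblast, -0.0545 (0.817) for extraembryonic endoderm, 0.596 (0.0571) for neuroectoderm and 0.0715 (0.751) for fibroblast and feeder markers. They were -0.288 (0.177) for interferon response, 0.0508 (0.512) for p53 targets, -0.126 (0.244) for heat shock, -0.0805 (0.601) for immediate early genes, 0.0706 (0.457) for ERK feedback, 0.0753 (0.177) for LIF and BMP targets, 0.356 (0.401) for retinoic acid and Hox, and -0.129 (0.457) for epithelial to mesenchymal genes. Mean, median and test did not share a sign in 4 of the 20 lists (THO and TREX, trophectoderm and trophoblast, extraembryonic endoderm, p53 targets).

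Over all 19305 genes limma called 0 after Thoc2 siRNA, and the smallest adjusted p was 0.207. At an unadjusted p under 0.05 there were 2817 genes, 1563 higher and 1254 lower, against 965 that chance gives. With quantile normalization there were 2798, of which 1115 were higher; with normexp there were 838, fewer than chance gives, and with 1 array left out 1816 to 4131. With an intensity trend and robust variances limma called 4 genes, 1 higher and 3 lower. Edn2, which encodes the peptide endothelin, was higher (2.92 ± 0.18), and Lefty1 and H2-K1 (-1.69 ± 0.14), an MHC class I heavy chain gene, were lower. Every other setting called 0 genes. Of the THO and TREX list no member passed: Ddx39b, the RNA helicase that works with THO, was at 0.61 ± 0.21, Ddx39a at 0.47 ± 0.15, Thoc6 at 0.45 ± 0.17 and Alyref, an export adaptor, at 0.24 ± 0.13, which was -0.23 with normexp background correction. Thoc7 was at -2.59 (SE 1.3), and that value came from replicate 1 of Thoc2 siRNA: without it Thoc7 stood at -0.65, and without replicate 2 at -4.53.

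What changed with Thoc5 siRNA was asked in the same way. The p53 target list rose: 23 of its 28 members lay above 0 (adjusted p = 0.177 with an estimated correlation). Adjusted over the list alone 8 members rose and 1 fell. Mdm2, the ubiquitin ligase that limits p53, was at 1.19 ± 0.17, Btg2, an antiproliferative gene, at 1.19 ± 0.16, Ccng1 at 1.04 ± 0.17, Plk2 at 1.52 ± 0.20 and Perp, an effector of cell death, at 1.46 ± 0.20, while Cdkn1a, which encodes the cell cycle inhibitor p21, was at 0.07 ± 0.15. The member that fell was Gdf15 (-0.76). Immediate early genes rose as a list (adjusted p = 0.545 with an estimated correlation), a call lost in 9 of 21 settings. Of its 24 members 7 rose when p-values were adjusted over the list alone, with Fosl1 at 1.57 ± 0.24, Ccn1 at 1.56 ± 0.31, Atf3 at 1.38 ± 0.24 and Jun at 1.17 ± 0.19, while Egr1 fell (-0.71 ± 0.15). The pluripotency list fell, with 32 of 39 members below 0 (adjusted p = 0.545 with an estimated correlation). The median of all genes was itself below 0 (-0.0857). Lefty1 was at -2.57 ± 0.14, Lefty2 at -2.31 ± 0.28, Dppa3 at -1.87 ± 0.16, Fbxo15 at -1.21 ± 0.17 and Tcl1 at -1.09 ± 0.15, and these 5 fell when p-values were adjusted over the list alone. The median of the pluripotency list differed from that of all genes by -0.163, against -0.327 for its mean. Within the slide that held both groups Lefty1 was at -2.54, Dppa3 at -1.98, Plk2 at 1.56, Perp at 1.75, Btg2 at 1.38 and Fosl1 at 1.92.

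The integrated stress response list also fell after Thoc5 siRNA, with 19 of 25 members below 0 (adjusted p = 0.545 with an estimated correlation), a call lost in 7 of 21 settings. Here too the median of all genes lay below 0 (-0.0857). Adjusted over the list alone 7 members fell, among them Chac1 (-2.11 ± 0.45) and the enzyme genes Psat1 (-1.49 ± 0.22), Cth (-1.27 ± 0.16) and Phgdh (-1.14 ± 0.17), and Atf3, which is in this list too, rose. Among the fixed pluripotency factors Pou5f1 was at -0.88 ± 0.22, Sox2 at -0.52 ± 0.19, Nanog at -0.50 ± 0.16, Zfp42 at -0.49 ± 0.22, Klf4 at -0.36 ± 0.16 and Esrrb at -0.27 ± 0.17, and none passed the threshold. Of the lineage genes Gata6 was at 1.40 ± 1.23, Cdx2 at 0.52 ± 0.30, T at -0.59, Sox1 at -0.15 ± 0.80, Gata4 at -0.08 ± 0.92 and Fgf5 at -0.02 ± 0.37, none past the threshold. Cdx2 was at 0.23 without NT replicate 1 and 0.25 without Thoc5 replicate 2, and Zfp42 at -0.27 without the latter. Gata6 was at -0.16 without NT replicate 2 and at 2.97 without NT replicate 1. Without Thoc5 replicate 1 Gata6 was at 0.47 and T at 0.07, and without Thoc5 replicate 2 they were at 2.34 and -1.25. Normexp background correction turned the signs of T (0.81), Sox1 (0.91), Gata4 (0.84) and Fgf5 (0.62).

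Against all other genes the p53 target list was higher by 0.559 in the mean after Thoc5 siRNA (camera adjusted p = 1.24e-06; adjusted p = 0.177 with an estimated correlation), and immediate early genes by 0.428 (0.0395; adjusted p = 0.545 with an estimated correlation). The pluripotency list differed by -0.327 (0.00333; adjusted p = 0.545 with an estimated correlation) and the integrated stress response list by -0.383 (0.0395; adjusted p = 0.545 with an estimated correlation). With slide as a random block the differences were 0.541 (p53 targets), 0.449 (immediate early), -0.364 (pluripotency) and -0.391 (integrated stress response), and within the shared slide 0.494, 0.485, -0.478 and -0.387. Every one of these signs held with any 1 array left out. The p53 call stood with any 1 array left out and ended with normexp background correction (0.112, adjusted p 0.0734). Pluripotency was not called without NT replicate 2 (-0.282, 0.0614) or Thoc5 replicate 2 (-0.234, 0.101) and stood at -0.493 without the dim Thoc5 replicate 1. Immediate early genes were not called without NT replicate 2 (0.405, 0.16), Thoc2 replicate 2 (0.377, 0.0713), Thoc5 replicate 1 (0.404, 0.0979) or Thoc5 replicate 2 (0.38, 0.0664), nor with normexp (0.1), with no filter on dim probes (0.29) or with the stricter filter (0.365). The integrated stress response was not called without NT replicate 1 (-0.285, 0.114), NT replicate 2 (-0.511, 0.0614) or Thoc5 replicate 2 (-0.336, 0.123), nor with quantile normalization (-0.371, 0.0749) or cyclic loess (-0.38, 0.0613). With normexp pluripotency stood at -0.857 and the integrated stress response at -0.801.

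Genes of the 16 lists that did not pass after Thoc5 siRNA moved in both directions when p-values were adjusted over the list alone. Of primitive streak and mesoderm genes 5 rose and 3 fell, with the signal gene Wnt3 at 1.75 ± 0.24 and the receptor gene Kdr at 1.24 ± 0.22, and Meox1 at -1.48 ± 0.27. Of trophectoderm genes Gata3 (1.85 ± 0.17), Tead4 (1.53 ± 0.18) and Hand1 (1.16 ± 0.20; well above background on 1 of 2 NT arrays) rose and the imprinted gene Phlda2 fell (-1.69 ± 0.23). Of formative and primed epiblast genes 3 fell: the DNA methyltransferase gene Dnmt3a (-1.25 ± 0.16), the transcription factor gene Otx2 (-1.03 ± 0.17) and Zic5, not well above background with Thoc5 siRNA and at least 2.14-fold lower. Of the ERK feedback list Phlda1 (1.73 ± 0.16), Dusp6 (0.87 ± 0.19), Etv4 (0.73 ± 0.16) and Fosl1 rose, and Spry1 (-0.69 ± 0.16) and Il17rd (-0.64) fell. Of the 2-cell-like and germline list Taf7l (2.15 ± 0.24) and Slc25a31 (1.52 ± 0.24) were among 4 that rose, and Dppa3 and Prdm1 (-1.56 ± 0.20) fell. Markers that feeder fibroblasts would bring moved both ways, with Thbs1 at 2.06 ± 0.28, Vim at 0.76 ± 0.14, Thy1 at -2.01 ± 0.39 and Fn1 at -0.87 ± 0.17. The lists' mean differences from all genes, each with its camera adjusted p, were 0.0626 (0.568) for THO and TREX, -0.159 (0.278) for formative and primed epiblast, 0.145 (0.29) for trophectoderm and trophoblast, 0.448 (0.0946) for extraembryonic endoderm, 0.246 (0.118) for primitive streak and mesoderm, 0.254 (0.278) for neuroectoderm, -0.189 (0.639) for fibroblast and feeder markers and -0.509 (0.123) for interferon response. They were 0.0376 (0.785) for heat shock, 0.376 (0.233) for ERK feedback, 0.112 (0.257) for LIF and BMP targets, -0.068 (0.192) for cell cycle, 0.223 (0.278) for retinoic acid and Hox, -0.0807 (0.589) for 2-cell-like and germline, 0.116 (0.308) for epithelial to mesenchymal genes and -0.0535 (0.507) for reference genes. Mean, median and test did not share a sign in 2 lists (heat shock, 2-cell-like and germline).

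Over all 19305 genes limma called 0 after Thoc5 siRNA, and the smallest adjusted p was 0.1. At an unadjusted p under 0.05 there were 3775 genes, 1438 higher and 2337 lower; with normexp there were 983, and with 1 array left out 2031 to 3547. With an intensity trend and robust variances limma called 660 genes, 256 higher and 404 lower, and with the main settings 543 of the 15057 genes well above background on all arrays; every other setting called 0. The genes with the extreme folds among those 660 were chosen after the counts were seen. On the higher side they were Amotl1 (2.96 ± 0.36), a regulator of Hippo signalling, Fbp2 (2.91 ± 0.62), a gluconeogenic enzyme gene, Pax1 (2.90 ± 0.28), Adamts3 (2.71 ± 0.21), a procollagen protease gene, Itga8 (2.51 ± 0.23), an integrin gene, Wnt10a (2.45 ± 0.21), Insm1 (2.28 ± 0.25) and Svop (2.27 ± 0.33). On the lower side they were Serpinf1 (-2.91 ± 0.35), Lefty1, Nupr1 (-2.54 ± 0.42), a stress-induced chromatin protein gene, Selenbp1 (-2.33 ± 0.24), Spn (-2.33 ± 0.28), Lefty2, Tekt1 (-2.26 ± 0.27) and the fructose transporter gene Slc2a5 (-2.25 ± 0.27). Pax1 was well above background on 1 of the 2 NT arrays, and Serpinf1 on 1 of the 2 Thoc5 siRNA arrays.

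**Figure D2:**
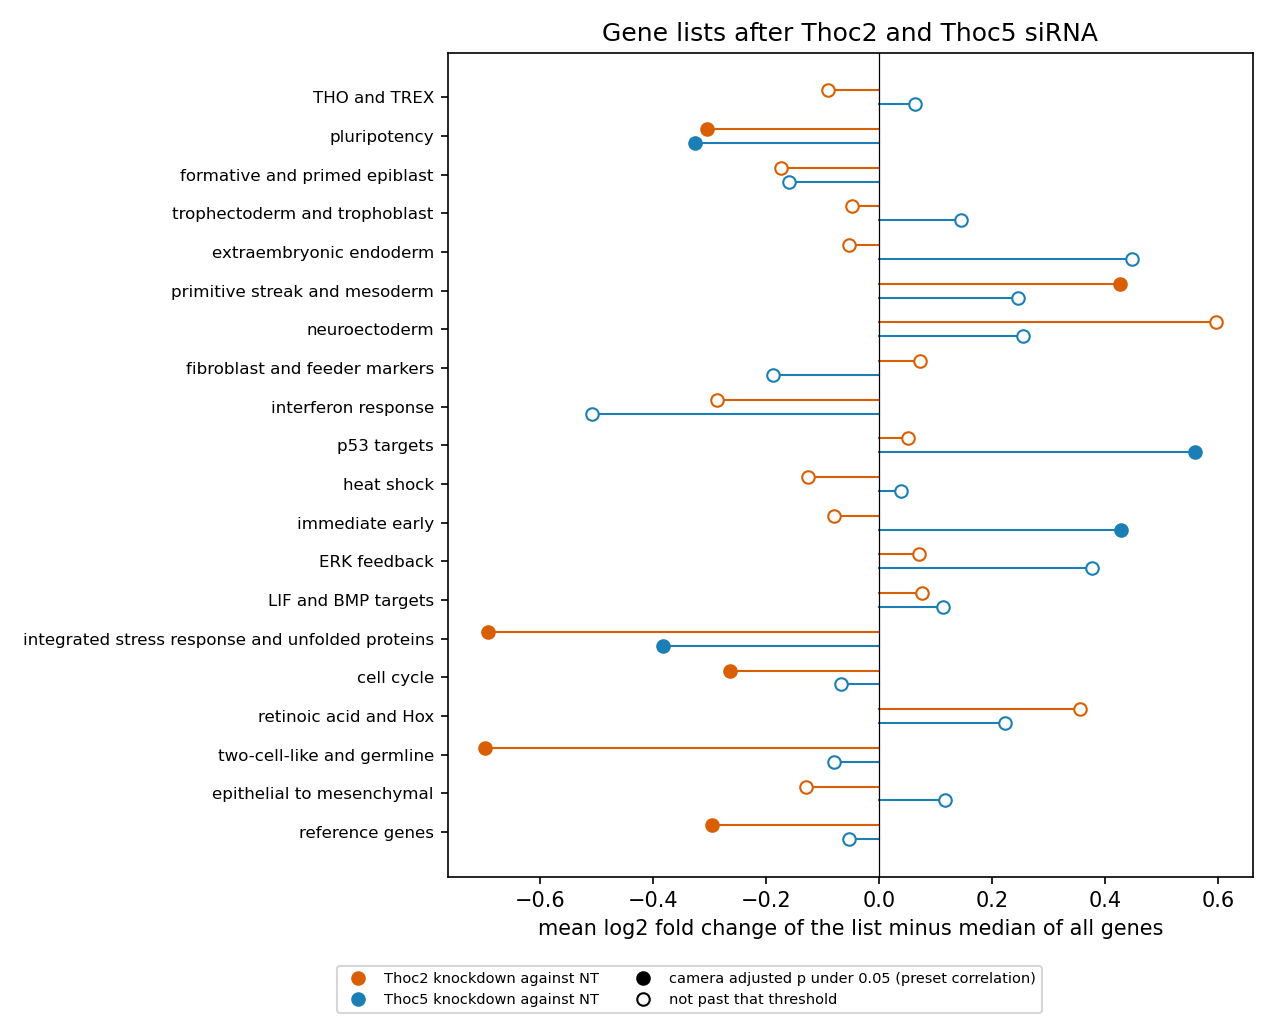
Mean log2 fold change of each of the 20 gene lists minus the median of all genes, for Thoc2 siRNA (orange) and Thoc5 siRNA (blue) against NT; filled points are lists with a camera adjusted p under 0.05 at the preset correlation. The integrated stress response and pluripotency lists lie below 0 with both siRNAs (-0.693 and -0.383, -0.305 and -0.327), and p53 targets lie at 0.559 with Thoc5 siRNA and at 0.0508 with Thoc2 siRNA; with an estimated correlation 0 lists passed.

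Whether the knockdowns differed from each other was tested directly, as Thoc5 siRNA minus Thoc2 siRNA. The p53 target list was higher with Thoc5 siRNA, with 25 of 28 members above 0 (adjusted p = 0.084 with an estimated correlation), among them Btg2 (1.26 ± 0.16), Mdm2 (0.91 ± 0.17) and Plk2 (0.84 ± 0.20). Immediate early genes were higher too (adjusted p = 0.422 with an estimated correlation): Atf3 (1.77 ± 0.24), Fosl1 (1.32 ± 0.24), Btg2 and Jun (0.84 ± 0.19) passed when p-values were adjusted over the list alone. In the 2-cell-like and germline list 6 of 23 members were higher by the same test, among them Zscan4c (3.28 ± 0.59), Usp17la (2.12 ± 0.52), the germ cell gene Taf7l (2.003 ± 0.24) and Dazl (0.89 ± 0.21). Six3 was lower with Thoc5 siRNA (-3.90 ± 0.58), where it was well above background on 1 of 2 arrays, as was Cth (-0.90 ± 0.16). Zscan4c stood at scaled log2 levels of 2.26 and 1.35 with NT siRNA, -3.38 and -3.46 with Thoc2 siRNA and 0.60 and -0.88 with Thoc5 siRNA. Against NT it was at -1.95 with Thoc5 siRNA, and at -1.21 without Thoc5 replicate 2.

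Against all other genes p53 targets were higher by 0.488 in the mean (camera adjusted p = 4.35e-11; adjusted p = 0.084 with an estimated correlation), the 2-cell-like and germline list by 0.597 (5.05e-07; adjusted p = 0.422 with an estimated correlation) and immediate early genes by 0.488 (1.34e-05; adjusted p = 0.422 with an estimated correlation). These 3 calls stood with any 1 array left out and in every other setting except the estimated correlation; with normexp the 2-cell-like list was at 0.318 and immediate early genes at 0.304. Epithelial to mesenchymal genes (0.225, 0.0287; adjusted p = 0.422 with an estimated correlation), extraembryonic endoderm (0.482, 0.0304; adjusted p = 0.836 with an estimated correlation) and reference genes (0.222, 0.0304; adjusted p = 0.519 with an estimated correlation) passed as well, and each lost its call in at least 10 of 20 settings. Without Thoc5 replicate 1 extraembryonic endoderm turned to -0.102 (adjusted p 0.945) reference genes stood at 0.0994 (0.791) and epithelial to mesenchymal genes at 0.218 (0.0793). Without Thoc5 replicate 2 extraembryonic endoderm stood at 0.983 and epithelial to mesenchymal genes at 0.182 (0.0533). Without Thoc2 replicate 1 extraembryonic endoderm stood at 0.312 (0.263) and reference genes at 0.225 (0.066), and without Thoc2 replicate 2 extraembryonic endoderm at 0.501 (0.0793) and epithelial to mesenchymal genes at 0.145 (0.109). With slide as a random block the 6 differences were 0.493 (p53 targets), 0.642 (2-cell-like), 0.508 (immediate early), 0.233 (epithelial to mesenchymal), 0.727 (extraembryonic endoderm) and 0.225 (reference genes, adjusted p 0.0543). No slide held both siRNAs, so no within-slide value exists. The other 14 lists did not pass, and mean, median and test did not share a sign in 5 of the 20. Limma called 0 genes here, with 1775 at an unadjusted p under 0.05 (424 higher, 1351 lower; 888 higher of 1638 with quantile normalization) and 0 with every other setting. With normexp 45 genes had an unadjusted p under 0.05, fewer than the 965 of chance, and with 1 array left out 1045 to 3073. The smallest adjusted p was 0.396.

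The mean of both knockdowns against NT averages the fold changes of both siRNAs, so a list can pass in it through 1 siRNA alone. Lefty1 (-2.48 ± 0.12), Lefty2 (-2.34 ± 0.24), Dppa3 (-1.93 ± 0.14), Fbxo15 (-1.03 ± 0.15), Tcl1 (-0.75 ± 0.13) and Tex19.1 (-0.68 ± 0.13) fell in the pluripotency list when p-values were adjusted over the list alone. In the integrated stress response list 6 genes fell by that test, among them Psat1 (-1.26 ± 0.19), Phgdh (-0.97 ± 0.15), Cth (-0.83 ± 0.14) and Trib3 (-0.75 ± 0.14). In the p53 list Perp (1.13 ± 0.17), Plk2 (1.10 ± 0.17), Ccng1 (0.84 ± 0.15) and Mdm2 (0.73 ± 0.15) rose. That list stood at 0.559 with Thoc5 siRNA and at 0.0508 with Thoc2 siRNA; the direct test of the difference gave an adjusted p = 0.084 with an estimated correlation. Perp was at 0.80 and Plk2 at 0.68 with Thoc2 siRNA. Against all other genes the integrated stress response list differed by -0.541 (camera adjusted p = 0.000679; adjusted p = 0.358 with an estimated correlation), the pluripotency list by -0.319 (0.00339; adjusted p = 0.51 with an estimated correlation) and p53 targets by 0.302 (0.00232; adjusted p = 0.358 with an estimated correlation). The median of the pluripotency list differed from that of all genes by -0.193. With slide as a random block the mean differences were -0.557 (integrated stress response), -0.349 (pluripotency) and 0.29 (p53 targets). The p53 call ended without Thoc2 replicate 2 (0.241, 0.0638), and with normexp background correction the difference was -0.0703 (0.767); with no filter on dim probes it was 0.17. Quantile normalization ended the call of pluripotency (-0.237, 0.0762). With normexp pluripotency stood at -0.832 and the integrated stress response at -0.87. The other 17 lists did not pass, and mean, median and test did not share a sign in 3 of the 20. Limma called 0 genes, with 3722 at an unadjusted p under 0.05 (1715 higher, 2007 lower), and the smallest adjusted p was 0.104. The unadjusted count was 1392 with normexp and 1669 without both arrays that stand apart. An intensity trend with robust variances gave 640 genes (264 higher, 376 lower), the filter for genes well above background on all arrays 465, and every other setting 0. Tbx18, a mesodermal transcription factor gene not well above background on the NT arrays, was at least 3.46-fold higher with Thoc2 siRNA and at least 3.41-fold higher with Thoc5 siRNA. Edn2 (2.45), Skor1 (2.39), Aox1 (2.29; well above background on 1 of 2 NT arrays) and Gata3 (2.12) were also higher among the genes the trend fit called.

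Across genes the fold changes of both knockdowns correlated at 0.512 (genes are not independent replicates). Both share the same NT arrays, and 100 simulated data sets with no effect gave 0.499 on average. At the main settings the correlation by itself therefore lay at what shared controls give. It was 0.910 with normexp, 0.686 with the stricter filter on dim probes and 0.340 to 0.717 with 1 array left out. The simulation covered the main settings only. The covariance was 0.260 against 0.138 in the simulation. The spread of the 2 NT arrays alone gave a covariance of 0.215, which leaves 0.0450. Genes higher with both siRNAs at an unadjusted p under 0.05 numbered 807 and genes lower with both 942, and 18 went opposite ways. Independent lists of these sizes would share 116 and 152. In 100 simulated data sets with no effect and shared NT arrays 140 and 142 genes overlapped on average (at most 166 and 168), where independent lists gave 11.4 and 11.6. The simulated lists held 942 and 943 genes against the 2817 and 3775 observed, so these overlaps are not on the same footing. How much of the excess comes from the shared controls cannot be told from them. With a separate NT array for each knockdown the correlation was 0.265 (NT replicate 1 for Thoc2) and -0.0875 (NT replicate 2 for Thoc2), and within the shared slides 0.322. Lefty1, Lefty2 and Dppa3 were below both NT arrays on all 4 knockdown arrays, and Gata3 and Phlda1 above. These genes were named for their small p or large fold on the same arrays, so their separation is not independent evidence.

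**Figure D3:**
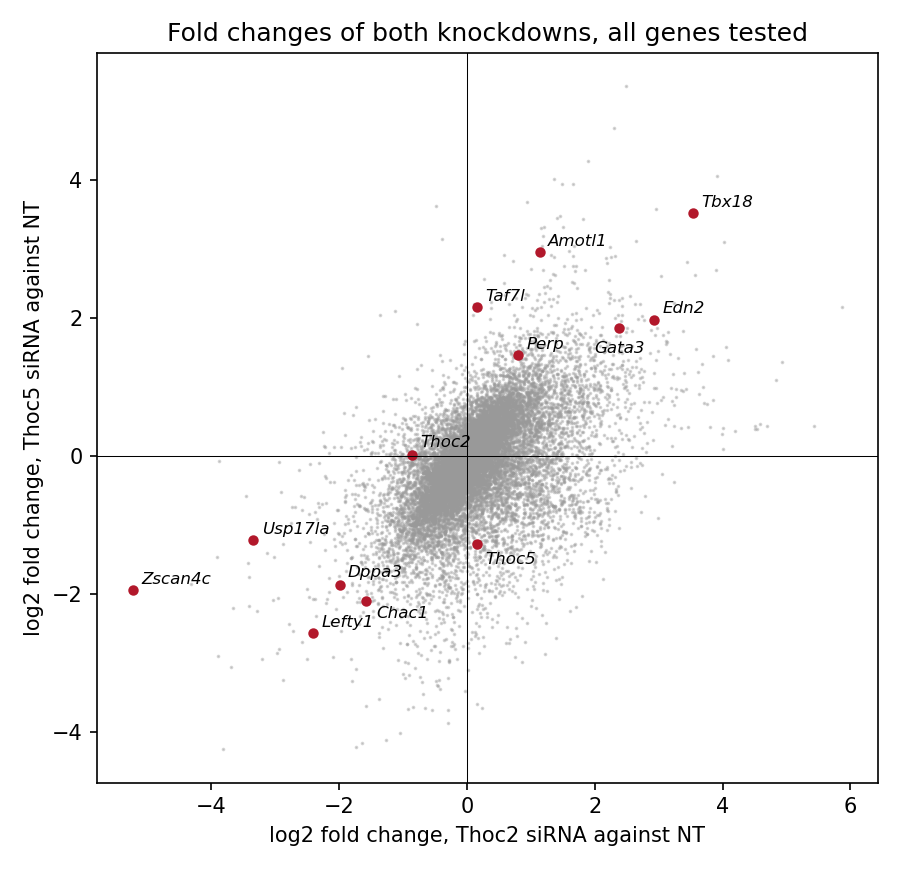
Log2 fold change of every one of the 19305 genes tested with Thoc2 siRNA (horizontal) and Thoc5 siRNA (vertical) against the same 2 NT arrays; red points carry the names of 13 genes. Lefty1, Dppa3 and Chac1 lie low in both directions, Edn2 and Gata3 high in both, and Zscan4c lies farther left (-5.23) than down (-1.95); the correlation of 0.512 stands beside 0.499 from shared controls with no effect.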

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

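Cyclic loess, the fits without both arrays that stand apart, and the matched random lists for the lists of abundant genes and with normexp were chosen only after the results were seen. In 6 gene lists the 2 siRNAs differed by the direct test of Thoc5 against Thoc2 siRNA, which is why they are listed here. The differences from all genes were 0.488 for p53 targets, 0.597 for the 2-cell-like and germline list, 0.488 for immediate early genes, 0.482 for extraembryonic endoderm, 0.225 for epithelial to mesenchymal genes and 0.222 for reference genes. With an estimated correlation 0 of the 6 passed (smallest adjusted p = 0.084, p53 targets). Extraembryonic endoderm turned to -0.102 without the dim Thoc5 replicate 1.

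The p53 targets Mdm2, Plk2, Perp, Ccng1 and Btg2 rose with Thoc5 siRNA, and 3 technical sources were tested. With only the brighter Thoc5 replicate 2 the list kept 85% of its difference (0.475), which speaks against the dim replicate 1 as the source. Its mean lay above 100% of 10000 random lists matched on mean level (0.473 against a highest of 0.3), also with normexp (0.348 against a matched mean of -0.138), which speaks against a trend with signal level, although with normexp the difference from all genes was 0.112 and lost its call (adjusted p 0.0734), and in the mean of both siRNAs it was -0.0703. The list was examined because it was high on these arrays, and the random genes were drawn independently, so that 100% is not a p-value. Of the list's 28 members 89.3% lay above the median of all genes, which speaks against a few genes. Higher p53 activity with Thoc5 siRNA may account for it, but Cdkn1a at 0.07 did not join, an siRNA effect apart from Thoc5 was not tested, and the estimated correlation leaves the list at an adjusted p of 0.177.

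Zscan4c and Usp17la were lower with Thoc2 than with Thoc5 siRNA. The mean over Zscan4c, Tcstv1, Tcstv3 and Zfp352 kept 116% of the difference with only Thoc2 replicate 2 (0.514 against 0.444), but Zscan4c alone (3.28) carries that mean, so the value speaks against replicate 1 as the source for that 1 probe only. Outside the Zscan4 family the 4 genes had a median of -1.1 with Thoc2 siRNA against NT, but that bound concerned NT and did not settle the difference between the siRNAs: Thoc5 minus Thoc2 was -0.247 in the median (Tcstv1 -0.52, Tcstv3 -1.01, Zfp352 0.03, Usp17la 2.11). The difference could therefore rest on the Zscan4 probes and Usp17la, and whether 2-cell-like cells were fewer stays open. Cross-hybridization of near-identical Zscan4 copies remains possible.

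The pluripotency, cell cycle, reference and integrated stress response lists hold abundant mRNAs, and all 4 were lower with Thoc2 siRNA. Cyclic loess, which removes trends with signal level, left 82.4% of their differences in the median (82.7%, 82%, 81% and 93.9% in that order), but quantile normalization left -0.19 of -0.305 (pluripotency), -0.164 of -0.264 (cell cycle), -0.189 of -0.296 (reference genes) and -0.615 of -0.693 (integrated stress response), so how much such a trend accounts for depends on the method. With normexp background correction the differences grew instead, to -0.804 (pluripotency), -0.653 (cell cycle) and -0.69 (reference genes). All 4 of 4 lists kept over 50% with only Thoc2 replicate 2 (-0.422, -0.263, -0.336 and -0.764). Random lists matched on mean level averaged -0.0424, -0.0308, -0.0373 and -0.0261, below the median of all genes (0.0599). The 4 lists themselves averaged -0.245, -0.204, -0.236 and -0.633. Signal level may therefore account for a part of the differences. Of the matched lists 0.05%, 0.44%, 1.25% and 0% were lower. The 4 lists were examined because they were low on these arrays, and the random genes were drawn independently, so these shares are not p-values. Loess nevertheless ended 3 of the 4 calls (adjusted p 0.0858, 0.0858 and 0.0827), while the integrated stress response kept its call (1.46e-05), so for the other 3 a difference in scaling could still carry the call.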

How the results depend on the processing

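Cyclic loess, the fits without both arrays that stand apart, the crossed block and separate NT arrays were chosen only after the results were seen. With limma 0 genes passed in the 4 comparisons in every setting but 2: trend and robust variances gave 4 (Thoc2), 660 (Thoc5) and 640 (mean of both), and the stricter filter 543 (Thoc5) and 465 (mean of both), with fewer genes tested. At an unadjusted p, leaving out 1 array gave 1816 to 4131 genes for Thoc2, 2031 to 3547 for Thoc5, 1045 to 3073 between the siRNAs and 2499 to 4554 for the mean of both. Normexp gave 838, 983, 45 and 1392, and leaving out both arrays 1044, 1682, 1163 and 1669. The Thoc5 target (-1.272) passed with trend and robust variances, and ranged from -1.442 to -1.101 with 1 array left out; Thoc2 ranged from -1.048 to -0.6771. Counts of lists called are out of all 20 and include lists gained. For Thoc2 siRNA 6 lists were called, 2 each with quantile normalization, the series table and cyclic loess, and 3 to 7 with an array left out. For Thoc5 siRNA 4 were called, 9 with normexp and 1 to 4 with an array left out. Between the siRNAs 6 were called, 3 each with the stricter filter and cyclic loess, and 4 to 7 with an array left out. For the mean of both 3 were called; normexp gave 9, median centring 5, no filter 7, the mean of a gene's probes 7, leaving out both arrays that stand apart 6, and leaving out an array 3 to 7. An estimated correlation left 0 lists in all 4. Among the lists called, unadjusted fry p was 0.102 for cell cycle with Thoc2 siRNA and 0.0668 for immediate early genes with Thoc5 siRNA. Between the siRNAs it was 0.0509 (2-cell-like), 0.0906 (epithelial to mesenchymal), 0.74 (extraembryonic endoderm) and 0.213 (reference genes). For the other lists called fry p was 0.0489 or lower. Signs turned for extraembryonic endoderm between the siRNAs (-0.102 without Thoc5 replicate 1, -0.194 without both arrays; 0.983 without Thoc5 replicate 2) and for p53 targets in the mean of both (-0.0703 with normexp). The correlation of 0.512 was 0.9103 with normexp, 0.6861 with the stricter filter, 0.2985 without both arrays, 0.3221 within slides, 0.2647 and -0.08755 with separate NT arrays, and 0.3402 to 0.7169 with 1 array left out. Normexp moved the median of all genes from 0.0609 to 0.29 (Thoc2), from -0.0851 to 0.242 (Thoc5) and from -0.00932 to 0.268 (mean of both); no filter moved it to 0.165, 0.0527 and 0.123. Of 225 named gene values normexp turned 28 signs, leaving out NT replicate 2 15, and quantile normalization 5. The cause of these changes was not tested. The share of spots well above background, 56.7% on the dimmest array, limits what dim genes can show.

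Same-numbered deviations correlated at -0.2 (NT and Thoc2), 0.143 (NT and Thoc5) and 0.218 (Thoc2 and Thoc5), so no pairing by number held across all groups. NT replicate 1 shared a slide with Thoc2 replicate 2, and NT replicate 2 with Thoc5 replicate 2. The first 2 values therefore cannot be told apart from slide, and whether replicates were paired stays open. The replicate block gave 0 genes in each comparison (2766, 3260, 1507 and 3402 at an unadjusted p), 7, 5, 7 and 3 lists, targets at -0.8625 and -1.272, and a correlation of 0.5133. The crossed block gave 0 genes in each comparison (2729, 3748, 1971 and 3670 at an unadjusted p).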

Other observations

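The MHC class I list, the Nodal genes and the comparison of outermost probes were chosen only after values had been seen. Genes of MHC class I antigen presentation were lower with both siRNAs at the preset correlation of camera. Of 14 measured genes 13 lay below 0 with Thoc2 siRNA (mean difference -0.809, camera p = 1.15e-08; p = 0.112 with an estimated correlation) and 13 with Thoc5 siRNA (-0.735, 3.89e-05; p = 0.207 with an estimated correlation). The heavy chain genes H2-K1 (-1.69 and -1.72), H2-Q1 (-1.46 and -1.54) and H2-D1 (-1.07 and -0.93), the immunoproteasome gene Psmb9 (-1.01 and -1.08) and B2m (-0.89 and -0.69), the light chain, were low in both. The peptide transporter genes were at -0.05 and 0.73 (Tap1) and, with an SE of 1.2, at 1.01 and -0.56 (Tap2). The list was assembled because H2-K1 was seen among the genes that fell, so its p is not independent evidence.

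Lefty1 and Lefty2 are targets of Nodal signalling, so lower Nodal signalling could account for their fall. The median of 6 other genes under Nodal signalling was -0.419 in the mean of both siRNAs, past the bound of -0.3 set beforehand. Among them Skil (-0.90), Smad7 (-0.58) and Tdgf1 (-0.26) lay below 0, while Nodal (0.30) and Pmepa1 (0.49) lay above. Camera gave p = 0.249 for these genes (p = 0.323 with an estimated correlation). Apart, the siRNAs gave medians of -0.515 (Thoc2) and -0.324 (Thoc5), both past that bound, which was set for the mean of both. The mean difference from all genes was -0.629 with Thoc2 siRNA (camera p = 0.0567, and 0.146 with an estimated correlation). With Thoc5 siRNA it was -0.258 (camera p = 0.661, and 0.684 with an estimated correlation). For the difference between the siRNAs camera gave p = 0.0426 (p = 0.129 with an estimated correlation). Lefty1 was at -2.40 and -2.57, so the hypothesis stays open. By the mean difference and its p it was less borne out with Thoc5 siRNA.

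In 4869 genes with 2 or more probes well above background on all arrays, the outermost probes along the genome were compared. These need not lie at the ends of the transcript. The mean difference of the 3'-most minus the 5'-most probe was 1.24 and 1.35 on the NT arrays. On the knockdown arrays it was 1.05, 1.15, 1.12 and 1.08, a gap of -0.0932. After quantile normalization the gap was -0.0569, more than 50% of its size, so a trend with signal level may explain only a part. A change of transcript ends with lower THO could give such a gap, though it was not measured at those ends. RNA quality or labelling could give it too, and these arrays cannot separate the sources. With 2 arrays against 4 an exact two-sided p cannot go below 0.133.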
